A study of Mus musculus with 6 samples.

How the data were processed

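RNA sequencing libraries were made from the prefrontal cortex of C57BL/6J mice at postnatal day 56 with a stranded, poly(A)-selecting kit (TruSeq Stranded mRNA), per the labels' protocols. There were 3 wild-type samples and 3 samples heterozygous for Cyfip2, and each sample's genotype and number were taken from its title. Salmon 0.11.2, R 3.6.0, DESeq2 1.19.11 and the genome build GRCm38 are named in the submitters' processing notes, without the role of each. The annotation release and the filter that left 18160 genes are not given in the sources used here.

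The deposited values are a normalized signal per gene, of the kind DESeq2 gives: read estimates divided by a factor that differs between samples and genes, and not raw counts. Totals per sample were nearly equal, at 36.4 to 37.1 M (M for 1e+06). Low values clustered at multiples of a step that differed between samples, but the step also varied from gene to gene. Within a tolerance of 0.1 reads, 78.8% to 83.7% of the values up to 2 reads fell on whole reads, against 20.3% to 42.8% of the values of 10 to 20 reads. Whole reads could therefore not be recovered for most genes, and no count model was used. Whether transcript lengths entered the scaling is not given in the sources used here, and the factor of each gene is unknown. The most common step, 0.768 to 1.359 normalized counts per read, gave the implied depth of 27.2 to 48.1 M reads per sample, which is an estimate. The 10 most abundant genes took 8.40% to 9.69% of each sample's total, and mitochondrially encoded genes 8.13% to 9.47%.

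Normalized counts were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (limma-trend: a linear model per gene with genotype as the only term and variances shrunk toward a trend in expression level). Genes needed a mean of at least 10 over the 6 samples, no further scaling was applied, and p-values were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. Because the design had foreseen either raw or normalized counts, the branch for normalized values was followed and the edgeR test foreseen for counts was not run. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Group values are means of normalized counts with the SD over 3 samples. Exact permutation tests of 3 against 3 samples were two-sided and cannot go below p = 0.1. Intervals are 95% intervals from the moderated model, and the floor of 3 reads covers counting error only.

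Gene symbols came from the GENCODE gene table: 18122 of the 18160 identifiers matched and 38 did not. Positions are those of GENCODE M21 on GRCm38, the build the submitters' notes name. Before the data were examined, 34 gene lists were fixed (the WAVE and Arp2/3 complexes, actin and FMRP partners, synapses, ion channels, cortical layers and cell types, markers of neighbouring tissue, blood and RNA quality, metabolism and the neighbours of Cyfip2). They were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 34 lists. The tests were repeated with a correlation estimated for each list and with fry, which asks whether a list's genes move one way on balance and does not compare the list with other genes. Some genes stand in more than 1 list, such as Scn4b among sodium channels and striatal markers. Cyfip2 was left out of every list. Where members were adjusted over a list alone, no correction was made across the 34 lists.

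The genes named were fixed by a rule: Cyfip2, then up to 12 genes per direction past the threshold with a mean of at least 50 and no overlap between genotypes. Where fewer passed, each direction was filled up to 6 with the smallest unadjusted p under the same conditions. From the WAVE, Arp2/3, excitatory postsynapse, sodium channel, interneuron and neighbour lists, and from every list past camera, the 2 members with the smallest p were named, except for some that are not reported here. Gm6158, Gm7206, Cnot1, Tgtp2, Gm28661 and Gm28437 were named after their values were seen. So were some further list members (Cyfip1, Nckap1, Shank1, Shank3, Camk2a, Pvalb, Lamp5, Scn2a, Mbp, Arc, Drd1, Cux2, Rasd2 and Ddx3y).

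The alternatives fixed in advance were a trimmed-mean (TMM) rescaling, limma without the trend or with robust shrinkage, no filter or a mean of at least 50, pseudocounts of 0.5 and 5, a threshold of 0.1, the sample number as a block and leaving out each sample in turn. Array weights and a correction for GC content and transcript length, alone and with the block, were added after seeing the data. GC content and length were known for 99.8% of the tested genes. No pair of samples of 1 genotype agreed within counting noise: the mean chi-square per gene over 12390 genes lay between 9.82 and 27.6 and the median between 1.97 and 4.61. The procedure was tested on simulated libraries before it was run. Among 15134 genes, 11 were called falsely, beside 39, 58 and 66 correct calls of genes changed 1.25-, 1.5- and 2-fold. The changed genes were drawn from those with a mean of at least 50, and no gene changed 2-fold had the wrong sign. To see which genes could share reads, the distinct 31-base words of the transcripts of Cyfip2, Gm6158 and Gm7206 were searched in the transcripts of all other GENCODE M21 genes on both strands.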

Results

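The transcriptome of the prefrontal cortex was measured by RNA sequencing in adult C57BL/6J mice at postnatal day 56. Libraries came from 3 wild-type samples and 3 samples heterozygous for a Cyfip2 mutation. CYFIP2 is a subunit of the WAVE regulatory complex, which activates the Arp2/3 complex to nucleate branched actin filaments, and it also binds the fragile X protein FMRP. The question the design poses is how loss of one functional Cyfip2 allele changes gene expression in the adult prefrontal cortex. The table held normalized counts for 18160 genes, of which 15151 had a mean normalized count of at least 10 over the 6 samples and were tested. The read depth implied by the lowest values was about 48.1, 45.5 and 27.2 M reads in wild-type samples 1, 2 and 3, and 37.5, 35.1 and 32.1 M reads in heterozygous samples 1, 2 and 3. The labels do not say that the samples of a genotype came from separate animals, so each p-value measures only the spread between these samples.

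Cyfip2 mRNA fell in the heterozygous cortex. Cyfip2 (ENSMUSG00000020340) lies on the minus strand of chromosome 11 at 46193850 to 46312859 (GRCm38). Its normalized count was 44752 ± 1369 (SD, n = 3) in wild-type samples and 28834 ± 644 (SD, n = 3) in heterozygous samples. The heterozygous level was 64.4% of wild type, with a 95% confidence interval of 59.7% to 69.5%. The log2 fold change was -0.63 ± 0.05 (SE), with an adjusted p of 0.0027 by limma-trend, the smallest p of all genes tested. The 3 heterozygous values all lay below the 3 wild-type values, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 samples can give. The call was lost when limma shrank the variances without a trend in expression level, with an adjusted p of 0.15 at the same fold change; over the 17 alternatives the adjusted p lay between 0.00085 and 0.15.

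None of the 10 other tested genes of the WAVE regulatory complex passed an adjusted p of 0.05, and none did when adjusted over the list alone. Cyfip1, the close paralogue of Cyfip2, had a normalized count of 3176 ± 170 (SD, n = 3) in wild-type and 3207 ± 135 (SD, n = 3) in heterozygous samples. Its log2 fold change was 0.01, with a 95% confidence interval of -0.12 to 0.15. Nckap1, the direct binding partner of CYFIP proteins in the complex, had a log2 fold change of 0.02 with an interval of -0.12 to 0.16. The members with the smallest p were Abi3, at a log2 fold change of 0.31 ± 0.21 (SE), and Wasf3, at -0.025 ± 0.05 (SE). None of the 10 genes of the Arp2/3 complex passed either test: Actr3 had the smallest p, with a log2 fold change of 0.09 ± 0.08 (SE), followed by Arpc5 at -0.06 ± 0.06 (SE). The set tests gave adjusted p values of 0.98 for both lists by camera. In both lists the mean fold change was slightly positive and the median slightly negative. The 30 actin filament regulators and the 16 genes of FMRP and its translation partners held no member past the threshold either, with adjusted p values of 0.78 each by camera.

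**Figure D1:**
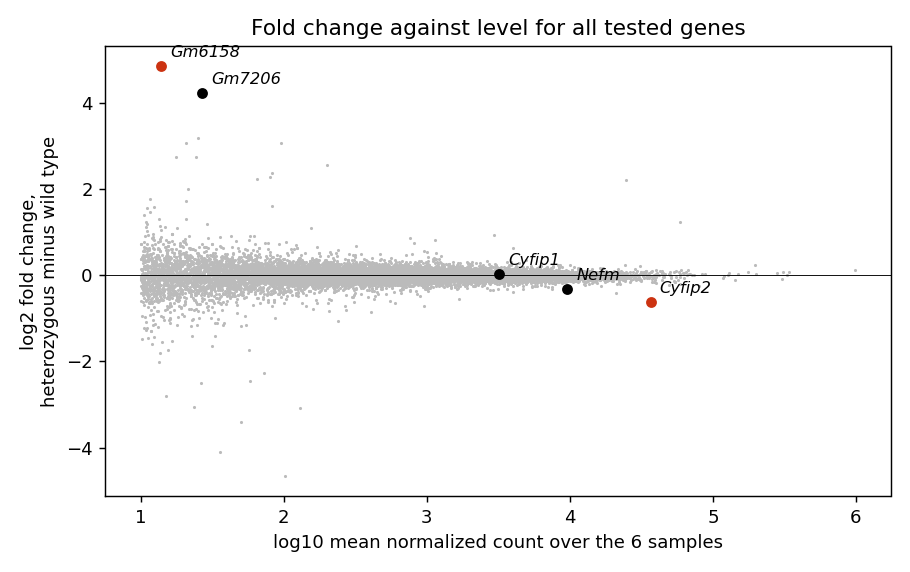
Each point is 1 of the 15151 tested genes, with the log10 of its mean normalized count over the 6 samples on the x axis and its log2 fold change (heterozygous minus wild type) on the y axis. Red points passed an adjusted p of 0.05 by limma-trend and black points are named genes that did not; Cyfip2 at -0.63 stands below the other genes of its level.

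Across the transcriptome, 2 genes passed an adjusted p of 0.05 by limma-trend: Cyfip2, which fell, and the processed pseudogene Gm6158, which rose. Gm6158 (ENSMUSG00000090381, chromosome 14, 24069734 to 24070637) lay outside the rule for named genes and is named after its values were seen. It was listed at 0 in all 3 wild-type samples and at 27.7 ± 2.23 (SD, n = 3) in heterozygous samples. Against a floor of 3 reads per wild-type library, valued at the most common step of each sample, Gm6158 was 9.45-fold higher. The factor of this gene is unknown, so that fold is not a strict lower bound. Its adjusted p was 0.014 by limma-trend. Most of its sequence is shared with the gene Cnot1, so reads cannot be assigned to it with certainty. The call was lost without heterozygous sample 1 (adjusted p = 0.24), without sample 2 (adjusted p = 0.24) and without sample 3 (adjusted p = 0.082). It was also lost with the sample number as a block (adjusted p = 0.059), alone and with GC and length correction (adjusted p = 0.089). Over all genes, 4 passed without wild-type sample 1, 4 without heterozygous sample 3 and 1 without heterozygous sample 1, Cyfip2 among them each time. The next smallest adjusted p in the transcriptome was 0.34. At an unadjusted p under 0.05 there were 768 genes, 357 higher and 411 lower in heterozygotes, where 758 are expected by chance. Splits of the 6 samples that mixed the genotypes gave 311 to 1583 such genes. With counts this variable, 768 beside 758 does not show that no other genes changed. The 2 genotypes did not overlap in 10.5% of the genes, against 10% by chance for 3 against 3. Libraries of the same depth and typical spread were also simulated, with 200 genes of 15134 tested changed. The same test recovered 58.2% of the genes with the weakest planted change, which was under 1.5-fold. It recovered 86.6% of those changed 1.5-fold and all 66 of those changed 2-fold. Each simulated gene had the typical spread of its level and varied independently of the others. Changes were planted only in genes with a mean of at least 50. Simulated genes of the same level did not differ in spread, and no variation was shared between genes. These shares may therefore overstate the power in the real samples. There, Myo18b did not pass at a log2 fold change of -1.01 (adjusted p = 0.55 by limma-trend), so changes of 2-fold could be missed.

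The other genes named by rule, the 6 higher and 5 lower ones with the smallest p, did not pass the threshold, and their values are given as measurements. Among genes lower in heterozygotes were Nefm, the medium neurofilament subunit, at 10717 ± 384 (SD, n = 3) in wild-type and 8509 ± 238 (SD, n = 3) in heterozygous samples, and Hapln4, a link protein of perineuronal nets, at 6420 ± 186 and 5351 ± 89.3 (SD, n = 3 each). Their log2 fold changes were -0.33 ± 0.05 and -0.26 ± 0.05 (SE), and their adjusted p values were 0.34 and 0.67 by limma-trend. The other lower genes were the myosin genes Myo18b, at a log2 fold change of -1.01 ± 0.17 (SE), and Myh7, at -0.38 ± 0.07 (SE), and the predicted gene Gm765, at -1.15 ± 0.22 (SE). Among genes higher in heterozygotes were Egfem1, at a log2 fold change of 0.69 ± 0.12 (SE), and Phykpl, a phospholysine lyase gene, at 0.49 ± 0.11 (SE). Ryr3, a calcium release channel of the endoplasmic reticulum, was at 0.43 ± 0.09 (SE), the amylase gene Amy1 at 0.36 ± 0.07 (SE), the ribosomal protein gene Rps15a at 0.35 ± 0.07 (SE), and Eml6 at 0.31 ± 0.06 (SE). Adjusted p values of these genes were between 0.55 and 0.67. On GRCm38, Nefm lies on chromosome 14 (68082590 to 68124846), Hapln4 on chromosome 8 (70083457 to 70090862), Egfem1 on chromosome 3 (29082023 to 29691209), and Eml6 and Phykpl on chromosome 11 (29743048 to 30026033 and 51584757 to 51604489).

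**Figure D2:**
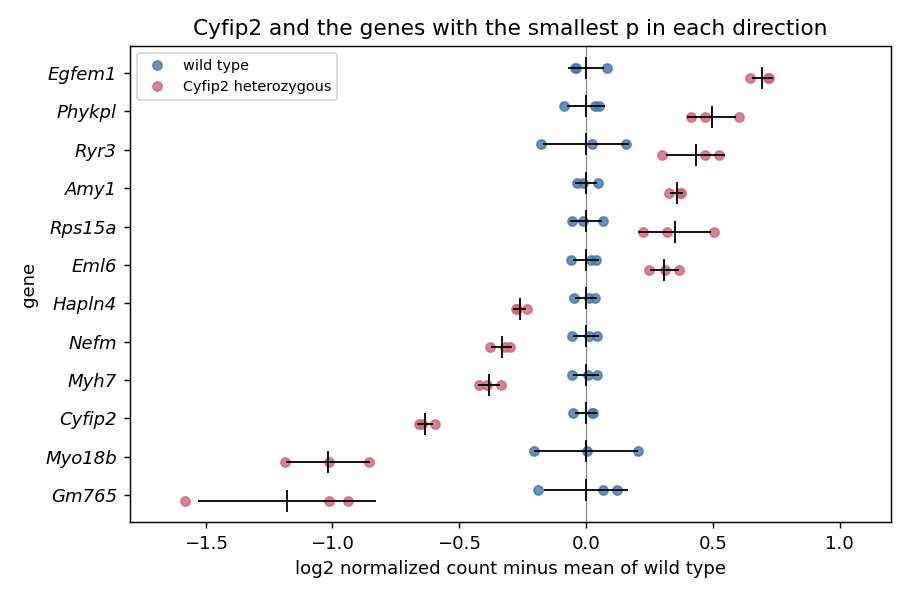
Points show each sample's log2 normalized count minus the mean of the wild-type samples (x axis) for Cyfip2 and the 11 genes with the next smallest p by the naming rule (y axis); vertical ticks are group means and horizontal bars are SD, n = 3 per genotype. The naming rule requires that the 3 heterozygous points of each gene lie on 1 side of its 3 wild-type points. Of these genes only Cyfip2 passed an adjusted p of 0.05.

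Gene lists fixed before the data were examined were compared next, to see whether groups of genes moved together. Of 34 lists, 15 passed the camera set test at its preset correlation of 0.01, 8 higher and 7 lower in heterozygotes. None passed when the correlation between the genes of a list was estimated from the samples, where the smallest adjusted p was 0.63 and the smallest unadjusted p was 0.081. Nor did any pass with fry, where the smallest adjusted p was 0.76. Camera with an estimated correlation can also be stricter for genes that do not vary together, so a lost call does not show that a list did not change. No gene in these lists passed the threshold over all genes. Members adjusted over a list alone were not corrected across the 34 lists, so some can pass there by chance. In 14 of the 15 lists the samples of the 2 genotypes overlapped in their list mean. Calls were also lost for potassium and HCN channels, astrocytes and microglia by limma without the trend, for potassium and HCN channels and microglia with GC and length correction, for microglia with that correction and the block, and for astrocytes, microglia, endothelial cells and striatal neurons with array weights, where the striatal median was -0.09.

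Genes of the excitatory postsynapse had 26 of 34 members below wild type and a median log2 fold change of -0.07 (adjusted p = 4.0e-04 by camera, 0.63 with an estimated correlation). Cacng2, an auxiliary subunit of AMPA receptors, had a log2 fold change of -0.19 ± 0.06 (SE). Shank1 and Shank3, scaffolds of the postsynaptic density, were at -0.16 ± 0.06 and -0.15 ± 0.06 (SE), and Camk2a at -0.11 ± 0.06 (SE). None of the 34 passed over the list alone. Wild-type sample 2 lay at -0.084 in the list mean, below the 3 heterozygous samples at -0.079 to -0.040, and the exact permutation p of the list mean was 0.4. In wild-type samples 1 and 2 the postsynaptic list mean was 0.06 and -0.08, where astrocyte markers were at -0.11 and 0.11 and endothelial markers at -0.15 and 0.13. Astrocyte, endothelial and meningeal markers were above wild type in heterozygotes for 18 of 20, 19 of 20 and 15 of 16 genes. For the postsynaptic list without wild-type sample 1, the median was -0.03 and the adjusted p 0.075. The list of voltage-gated potassium and HCN channels had 15 of 23 members below wild type and a median of -0.08 (adjusted p = 0.037 by camera, 0.69 with an estimated correlation). Kcnh1, its member with the smallest p, was at a log2 fold change of -0.18 ± 0.05 (SE). That list lost its call without wild-type sample 1 (median -0.023, adjusted p = 0.74), without wild-type sample 3 (median -0.05, adjusted p = 0.27) and without heterozygous sample 2 (median -0.018, adjusted p = 0.53), and its median was -0.15 without wild-type sample 2.

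Upper-layer markers of excitatory neurons had 13 of 16 members below wild type and a median log2 fold change of -0.11 (adjusted p = 0.0066 by camera, 0.63 with an estimated correlation). Adjusted over the list alone, 3 members passed: Scnn1a, a layer 4 marker, at a log2 fold change of -0.65 ± 0.16, Cux2 at -0.24 ± 0.07 and Lmo4 at 0.18 ± 0.05 (SE), none of which passed over all genes. Deep-layer markers had 17 of 19 members above wild type and a median of 0.09 (adjusted p = 0.0025 by camera, 0.63 with an estimated correlation). Ldb2 had a log2 fold change of 0.25 ± 0.08 (SE) and Rprm 0.30 ± 0.13 (SE), and no member passed over the list alone. Wild-type sample 3 stood apart from all other samples in both lists, at 0.15 in the upper-layer mean and -0.16 in the deep-layer mean. Without wild-type sample 2 the medians were -0.19 and 0.18. Without wild-type sample 3 the medians were -0.0011 and 0.037 and the adjusted p values 0.37 and 0.30. The upper-layer list also lost its call without heterozygous sample 2, with a median of -0.07 and an adjusted p of 0.055, and the deep-layer median was 0.06 there and 0.13 without heterozygous sample 3.

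GABAergic interneuron markers had 19 of 24 members above wild type and a median log2 fold change of 0.09 (adjusted p = 0.0052 by camera, 0.63 with an estimated correlation). Crhbp, a corticotropin-releasing hormone binding protein, was at a log2 fold change of 0.29 ± 0.08 (SE), and the neuropeptide gene Sst was at 4676 ± 52.4 normalized counts in wild-type and 5355 ± 323 in heterozygous samples (SD, n = 3 each). Of the 5 members below wild type, Lamp5 had the smallest p, at a log2 fold change of -0.23 ± 0.08 (SE). Pvalb, the marker of fast-spiking interneurons, was at -0.13 ± 0.07 (SE). None of the 24 passed over the list alone, and without wild-type sample 2 the median was 0.03 and the adjusted p 0.22. Voltage-gated sodium channel genes did not pass as a list (adjusted p = 0.19 by camera). Of the 8 members, Scn4b passed when adjusted over the list alone, at an adjusted p of 0.017. Its normalized count was 5994 ± 443 in wild-type and 4940 ± 273 in heterozygous samples (SD, n = 3 each), and its adjusted p over all genes was 0.73. Scn3b had a log2 fold change of 0.16 ± 0.08 (SE), and Scn2a one of 0.01 ± 0.08 (SE).

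Myelin and oligodendrocyte genes had 22 of 25 members below wild type, with a median log2 fold change of -0.11 (adjusted p = 4.3e-04 by camera, 0.69 with an estimated correlation). Mbp, the myelin basic protein gene, was at 64011 ± 12880 in wild-type and 54702 ± 2821 in heterozygous samples (SD, n = 3 each), and the smallest p values were those of Olig2 and Enpp2, at -0.21 ± 0.08 and -0.13 ± 0.06 (SE). Wild-type sample 2 held the highest myelin level, 0.29 above the wild-type mean, while the other wild-type samples lay at -0.13 and -0.15. Striatal markers, a sign of neighbouring tissue, were also highest in wild-type sample 2, at 0.22 against -0.05 and -0.17. Without wild-type sample 2 the median of the list turned to 0.037, with an adjusted p of 0.48, and without wild-type sample 3 it was -0.19. Astrocyte, microglial and endothelial lists had 18 of 20, 15 of 20 and 19 of 20 members above wild type, with medians of 0.05, 0.06 and 0.08 (adjusted p = 0.026, 0.037 and 0.016 by camera, 0.69 for each with an estimated correlation). Their members with the smallest p were Gfap at 0.31 ± 0.16 and Gjb6 at 0.27 ± 0.14 for astrocytes, Trem2 at 0.28 ± 0.13 and Cd68 at 0.22 ± 0.11 for microglia, and Abcc9 at 0.16 ± 0.11 and Slco1a4 at 0.099 ± 0.090 for endothelial cells and pericytes (log2 fold change ± SE). Without wild-type sample 1 these 3 medians were -0.0012, -0.0096 and 0.0064, and the adjusted p values 0.93, 0.88 and 0.97. Without wild-type sample 2 the medians were 0.11, 0.13 and 0.13, and without heterozygous sample 3 the astrocyte median was 0.08. Without heterozygous sample 2 the medians were 0.036, 0.044 and 0.034 and the adjusted p values 0.14, 0.29 and 0.42. The astrocyte list also lost its call without wild-type sample 3 (median 0.06, adjusted p = 0.052) and without heterozygous sample 1 (median 0.036, adjusted p = 0.32), and the microglial list without heterozygous sample 1 (median 0.05, adjusted p = 0.056). Meningeal and fibroblast markers had 15 of 16 members above wild type and a median of 0.17 (adjusted p = 2.7e-04 by camera, 0.63 with an estimated correlation). Slc6a20a, a transporter gene, passed over the list alone (adjusted p = 0.035) and was at 898 ± 62.8 normalized counts in wild-type and 1133 ± 87.5 in heterozygous samples (SD, n = 3 each), and Ogn was at a log2 fold change of 0.21 ± 0.09 (SE). The list kept its call without each sample, with a median of 0.07 without wild-type sample 1 and 0.11 without heterozygous sample 2.

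Of 78 cytosolic ribosomal protein genes, 62 were above wild type, with a median log2 fold change of 0.09 (adjusted p = 5.3e-11 by camera, 0.63 with an estimated correlation). Rps15a and Rpl32 passed over the list alone, at an adjusted p of 0.044 each, and Rpl32 was at 2473 ± 132 normalized counts in wild-type and 2959 ± 22.0 in heterozygous samples (SD, n = 3 each). Many of these genes have near-identical pseudogenes with which reads can be split, so single values are uncertain. The exact permutation p of the list mean was 0.7; the list mean was 0.23 in heterozygous sample 2 and -0.05 in heterozygous sample 1, which lay below all 3 wild-type samples. Mitochondrially encoded genes, a sign of RNA quality, were highest and lowest in the same 2 samples, at 0.17 and -0.12. The list kept its call without each sample, with a median of 0.06 both without heterozygous sample 2 and without wild-type sample 1, and of 0.13 without heterozygous sample 1. Of 22 cholesterol synthesis genes, 20 were above wild type, with a median of 0.09 (adjusted p = 4.0e-04 by camera, 0.63 with an estimated correlation). Fdft1, the squalene synthase gene, was at 0.18 ± 0.06 (SE) and Sc5d at 0.11 ± 0.05 (SE). Wild-type sample 2 lay at 0.098 in the list mean, above heterozygous samples 1 and 2 at 0.080 and 0.064. The exact permutation p of the list mean was 0.3. Among wild-type samples, astrocyte and endothelial markers were highest in sample 2 as well. The cholesterol list kept its call without each sample, with a median of 0.05 without wild-type sample 1 and 0.06 without wild-type sample 3. Circadian clock genes had 12 of 16 members below wild type and a median of -0.07 (adjusted p = 0.012 by camera, 0.63 with an estimated correlation), with Cry1 at -0.19 ± 0.08 and Bhlhe41 at -0.17 ± 0.08 (SE). That list lost its call without wild-type sample 3 (median -0.026, adjusted p = 0.48) and without heterozygous sample 2 (median -0.045, adjusted p = 0.093).

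Striatal neuron markers, fixed as a sign of neighbouring tissue in the dissection, had 12 of 18 members below wild type and a median log2 fold change of -0.19 (adjusted p = 0.0030 by camera, 0.63 with an estimated correlation). Ppp1r1b, Scn4b and Rasd2 passed over the list alone, and Ppp1r1b, which encodes the phosphoprotein DARPP, was at 3071 ± 204 normalized counts in wild-type and 2426 ± 171 in heterozygous samples (SD, n = 3 each). The dopamine receptor gene Drd1, in contrast, was at 244 in wild-type and 246 in heterozygous samples on average. Wild-type sample 2 had the highest list mean, 0.22 above the wild-type mean, and without it the median was -0.02 and the adjusted p 0.30; without heterozygous sample 1 the median was -0.07. Neighbours of Cyfip2 on chromosome 11 had 9 of 11 members below wild type and a median of -0.18 (adjusted p = 0.0066 by camera, 0.63 with an estimated correlation). Over all 62 other genes tested within 5 Mb of Cyfip2, a window chosen after the values were seen, 34 were below wild type and the median was -0.0069. The list of neighbours was the 1 list whose samples did not overlap between genotypes, with an exact permutation p of 0.1. Sgcd was at -0.65 ± 0.25 and Lsm11 at -0.25 ± 0.11 (log2 fold change ± SE), and no member passed over the list alone. The list lost its call without wild-type sample 1 (median -0.10, adjusted p = 0.052) and without heterozygous sample 2 (median -0.12, adjusted p = 0.093).

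**Figure D3:**
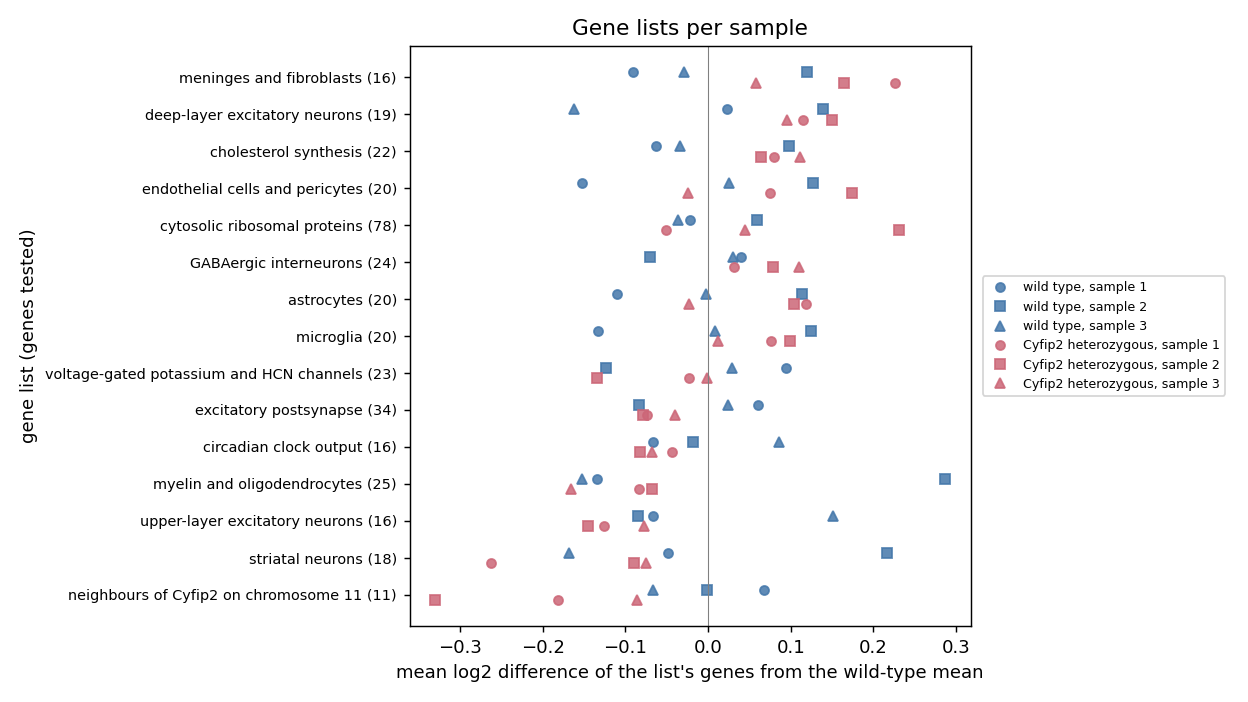
The y axis shows the 15 gene lists past the camera test at its preset correlation, with the number of genes tested. Each symbol is 1 sample's mean log2 difference from the wild-type mean over the genes of the list (x axis). Marker shapes are sample numbers, which are not known to pair samples. Wild-type sample 2 lies at 0.29 for myelin genes and wild-type sample 3 at -0.16 for deep-layer genes, and the genotypes overlap in every list except the neighbours of Cyfip2.

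The other lists did not pass the camera test. Activity-regulated immediate early genes had 14 of 23 members below wild type and an adjusted p of 0.66, and their wild-type list mean spread by 0.41 (SD, n = 3); Arc was at a log2 fold change of -0.42 ± 0.23 (SE). Genes of developmental epileptic encephalopathy had 24 of 37 members below wild type (adjusted p = 0.19), presynaptic release genes 20 of 30 (adjusted p = 0.42), GABA-A receptor and inhibitory postsynapse genes 12 of 18 (adjusted p = 0.093), and voltage-gated calcium channels 10 of 15 (adjusted p = 0.090). Oligodendrocyte precursor markers had 6 of 11 below wild type (adjusted p = 0.086), choroid plexus and ependymal markers 7 of 9 (adjusted p = 0.55), olfactory bulb and subcortical markers 8 of 14 (adjusted p = 0.45), and red blood cell genes 3 of 7 (adjusted p = 0.67). Among signs of RNA quality and stress, mitochondrially encoded genes had 4 of 13 below wild type (adjusted p = 0.19), nuclear oxidative phosphorylation genes 43 of 74 (adjusted p = 0.13), heat shock genes 9 of 14 (adjusted p = 0.19) and glucocorticoid response genes 7 of 16 (adjusted p = 0.42). The 4 Y-linked genes tested were expressed in all 6 samples, with Ddx3y at 1565 ± 184 in wild-type and 1768 ± 106 in heterozygous samples (SD, n = 3 each), and that list, with 4 of 4 members above wild type, had an adjusted p of 0.0502, just above the threshold.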

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

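Tests with array weights and with a GC and length correction were chosen after seeing the data, and the others were fixed in advance. Cyfip2 kept its direction in all 17 alternatives, with a log2 fold change between -0.66 and -0.61, and its adjusted p stayed under 0.05 in 16 of them; limma without the trend gave -0.63 at an adjusted p of 0.15, and the cause was not tested. Leaving out 1 sample gave -0.66 to -0.62. The count of 2 changed genes became 1 without the trend (Gm6158), 1 with a mean of at least 50, which removes Gm6158 by its low level, and 1 under the block with GC and length correction; leaving out 1 sample gave 1 to 4 genes, with 4 both without wild-type sample 1 and without heterozygous sample 3. Cyfip2 was among the genes called in each of these settings except limma without the trend. At an adjusted p under 0.1 there were still 2. The 15 gene lists became 0 with an estimated correlation and 0 with fry, and 9 to 19 when 1 sample was left out; 9 was without heterozygous sample 2. With the preset correlation, 10 of 165 list results lost their call over the other settings and none changed direction. Without wild-type sample 1 the microglial median turned to -0.0096, the astrocyte median to -0.0012 (-0.0012 to 0.11 over the samples left out), and the endothelial test turned at a median of 0.0064, and without wild-type sample 2 the myelin median turned to 0.037; over the samples left out the microglial, endothelial and myelin medians ranged from -0.0096 to 0.13, from 0.0064 to 0.13 and from -0.19 to 0.037. Cnot1, near 0 at 0.0038, turned to -0.0021 with GC and length correction, with and without the block, to -0.018 with array weights, and to -0.039 without wild-type sample 2 and without heterozygous sample 1 (-0.039 to 0.033 over the samples left out). Whether equal sample numbers pair samples could not be told. Deviations of equal numbers correlated at 0.13, 0.12 and -0.0052. Those of numbers 1 and 2 were the highest of all pairs across genotypes, while wild-type sample 3 correlated best with heterozygous sample 2. Deviations were taken from means of 3 samples, so these correlations are not independent and cannot settle the pairing. With the number as a block, 2 genes (Cyfip2 and Gm28437) and 19 lists were called, Gm6158 had an adjusted p of 0.059, and no list passed with an estimated correlation (smallest adjusted p 0.31) or fry (0.40). Rescaling by TMM called the same 2 genes. On simulated libraries, 58.2% of the weakest planted changes were recovered. In these, genes varied independently with the typical spread of their level, and changes were planted only in genes with a mean of at least 50.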

Other observations

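The estimated correlation as an account of the list calls, the splits by number of genes, the share of Cnot1, the families, the region around Cyfip2 and the genes of large fold are tests chosen after the results were seen. Beyond the fixed lists, gene families defined by the letters that open a symbol were compared. Of 66 families with at least 20 tested genes, 2 passed camera at the preset correlation: the Rpl family, with 63 genes and a median log2 fold change of 0.10, and the Rps family, with 58 genes and a median of 0.07. Neither passed with an estimated correlation (adjusted p = 0.94 for each). Both families take in genes of the fixed list of cytosolic ribosomal proteins, such as Rpl32 and Rps15a, so they are not evidence separate from that list. The 23 genes whose symbols open with Myo, Myo18b among them, had a median of -0.04 and an adjusted p of 0.27. Within 5 Mb of Cyfip2 on chromosome 11, 62 other genes were tested, of which 28 were higher and 34 lower in heterozygotes, with a median of -0.0069. Unadjusted p was under 0.05 for 8.06% of them and for 5.05% of genes elsewhere (Fisher's exact test, two-sided, p = 0.24). The smallest p in the window was that of the interferon-inducible GTPase gene Tgtp2, at a log2 fold change of 0.91 ± 0.29 (SE) and an adjusted p of 0.88.

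Of 22 tested genes with a log2 fold change of at least 2 in either direction, 11 are annotated pseudogenes, against 2.59% of all tested genes (Fisher's exact test, two-sided, p = 1.7e-12). Genes were not matched for level or spread in that test, and several of the 22 had an SD near or above the mean of a genotype. It therefore cannot tell pseudogenes apart from low or variable genes in general. Of the 22, 1 gene, Gm6158, passed the threshold. The pseudogene Gm28661 is an example at high level, at 7600 ± 6681 in wild-type and 41925 ± 52768 in heterozygous samples (SD, n = 3 each). Gm7206, on chromosome 14 like Gm6158, was at 131, 14.6 and 11.9 in the heterozygous samples and at 3.1, 0 and 0 in the wild-type samples. It shares 62.8% of its 31-base words with other genes, mainly Rpl9.

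Cyfip2 stood at 64.4% of wild type rather than at 50%, and the interval of 59.7% to 69.5% excludes a halving of the normalized count. Reads of other genes counted as Cyfip2 would have had to make up 28.9% of the wild-type value, and 0% of its 31-base words occur in another gene, Cyfip1 included, which argues against that source. A scaling factor per sample or the pseudocount as the source is argued against as well. The lowest log2 fold change under TMM rescaling or another pseudocount was -0.64, where a halving is -1. Cyfip2 lies far above the pseudocounts, so their part of the test could hardly come out otherwise. The factor specific to each gene in the deposited values is unknown and was not varied, so its part stays open. Transcripts of the targeted allele that keep part of the gene may be counted with it, or the intact allele may be expressed at a higher level; the table holds only gene totals (64.4% of wild type), so these cannot be told apart.

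Gm6158 was listed at 0 in the 3 wild-type samples and between 26.2 and 30.2 in the 3 heterozygous samples. Of its 31-base words, 92.8% occur in transcripts of Cnot1, a scaffold of the deadenylase complex on chromosome 8, so its values may be reads of Cnot1 or of an unannotated copy assigned to the pseudogene. Cnot1 itself was at 4547 ± 232 in wild-type and 4559 ± 244 in heterozygous samples (SD, n = 3 each), and Gm6158 amounts to 0.61% of it, too little to show in Cnot1. Whether the heterozygous animals carry a sequence variant or transcript that draws reads to the pseudogene cannot be told apart from this without reads. For the whole comparison, 2 of the 10 splits of the 6 samples, the split by genotype among them, gave at least 2 genes, with 3 as the highest of the other splits. These 10 splits are too few for a share under 0.05.

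The last pattern weighed is the set of 15 gene lists past camera at the preset correlation. None of them (0) kept its call with an estimated correlation, whose median over the 34 lists was 0.24. That test can also give a larger p where genes do not vary together. For the Myo family, at an estimated correlation of -0.02, the unadjusted camera p was 0.012 with the preset and 0.051 with the estimated correlation. Losing the calls is therefore weak evidence on its own. Counting the split by genotype itself, 4 of the 10 splits of the samples called at least 15 lists, with 18 as the highest of the other splits. These 10 splits are too few for a share under 0.05. Genes of a list varying together between samples of 1 genotype, as myelin genes did in wild-type sample 2, is a candidate explanation for the calls that these tests cannot settle. A trend with GC content and transcript length as the whole cause is argued against, since 13 of the 15 lists kept their call and direction after correction for both; the 2 that did not, potassium and HCN channels and microglia, had medians of -0.08 and 0.06 before and -0.07 and 0.05 after it. A small effect of genotype on these lists stays open, untested beyond these samples.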
